A study of Arabidopsis thaliana with 24 samples.

How the data were processed

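Leaf RNA of Arabidopsis thaliana was sequenced from 24 libraries in 8 groups of 3 biological repeats, made of 2 genotypes under 4 conditions. The genotypes were wild type Col-0 and wrky48-1, a T-DNA insertion line of the transcription factor gene WRKY48 in the same background. Light was set to 50 (control, heat) or 900 (high light, combination) µmol per square metre and second. Temperature was 23 °C in control and high light and 40 °C in heat and the combination. Each stress lasted 8 h on plants 30 days old. Per the labels' protocols, each repeat pooled leaves of at least 20 plants. The plants per treatment were given as 45, and it was not established whether this counts each repeat or whether pools shared plants. The SE and p-values therefore cover differences between pools, and it is not known how far these stand for separate experiments.

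The deposited values were a normalized signal per gene and library, that is, read counts divided by 1 size factor per library, and the authors made them with DESeq2 1.20.0 per the submitters' processing notes. Reads were checked with FastQC 0.11.7 and aligned with STAR 2.4.0.1 to the TAIR10 build, per the submitters' processing notes. Neither the counting tool nor the annotation release was stated in the sources used here. The table held 32833 loci. Every value of each column was a whole multiple of 1 step (100% of values, tolerance 0.001), so whole reads and size factors were recovered from the values themselves. Recovered reads per library ranged from 9.22 to 20.53 M and size factors from 0.651 to 1.6974. Intervals and floors given for counts cover counting error only, since PCR duplicates cannot be told from separate molecules. A floor is 3 reads over the 3 libraries of a group.

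Gene names came from a reference gene table of the TAIR10.1 assembly, matched on the locus identifier (32548 loci matched, 285 not matched), and no coordinates were used. Locus identifiers followed the deposited table.

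Differences were tested with limma 3.58.1 in R 4.3.3 (trend, not robust) on log2 of the deposited normalized count plus 1. The fit covered all 24 libraries and 8 groups without covariates, so that the groups shared an estimate of the spread. Genes with at least 10 normalized counts in at least 3 libraries were tested (20915 genes). P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The contrasts were each stress against control within each genotype, wrky48 against wild type within each condition, the differences between genotypes in each response, and the departure of the combination from the sum of the 2 single log2 responses in wild type. A further count took genes that differed in the same direction between the combination and each of control, high light and heat in wild type.

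Gene lists (20 lists, 385 loci) were fixed from textbook knowledge before the data were examined, the last 4 being markers of leaf cell types: heat shock proteins and chaperones, heat shock transcription factors, antioxidant enzymes, reactive oxygen response markers, light-harvesting proteins, Calvin cycle, photoprotection and photosystem II repair, flavonoid and anthocyanin synthesis, jasmonate synthesis, jasmonate signalling and response, salicylic acid and pathogenesis, abscisic acid synthesis and response, WRKY transcription factors other than WRKY48, endoplasmic reticulum unfolded protein response, circadian clock, senescence and chlorophyll breakdown, and markers of guard cells, phloem, epidermis and dividing cells. 1 list member had another name at its locus in the reference and was left out. For contrasts of 2 groups, 27 of the list medians had some members with a group at 0 reads, and setting these to their bound moved a median by at most 0.22. The list medians of the differences of responses and of the departure from the sum were not checked in this way. Lists were tested with camera at a preset inter-gene correlation of 0.01 and with the correlation estimated, with Benjamini-Hochberg adjustment over 220 tests. Of these, 110 were called with the preset value and 92 of the 110 with the estimated correlation. Genes named in the text are WRKY48, the 10 called genes with the largest rise and the 10 with the largest fall per contrast (a mean of at least 50 normalized counts in the higher group, a symbol, and for contrasts of 2 groups no overlap of the libraries), list members with the largest changes, and genes called with the same sign in all 4 genotype comparisons.

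The alternatives were pseudocounts of 0.5 and 5, no filter, rescaling of every library to the same total, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a fit restricted to the groups of the contrast, and leaving out each library in turn. Subtraction of a possible carry-over, and the rescaled share of genotype differences that lie against the wild type response, were added after the data had been seen. The tests were run first on simulated counts with known changes. For the genotype comparison under the combination, limma recovered 74% of 50 genes changed by 0.5 on the log2 scale and 100% of 50 changed by 1, with 0.2% of 19542 unchanged genes called. For the difference between genotypes in the combined response it recovered 44% and 92% at those sizes. Few genes were changed in the simulation, so these shares hold for that setting. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the preparation and figures. No deposited library was left out.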

Results

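Leaf transcripts were measured in 24 libraries from wild type Col-0 plants and plants of the insertion line wrky48-1. Plants were kept under control conditions, high light, heat, or high light plus heat, with 3 pooled repeats in each of the 8 groups. The series asks how the leaf transcriptome responds to each stress and to their combination, and how wrky48 plants differ in that response. Recovered reads per wild type library ranged over 10.93 to 13.92 M in control, 9.87 to 19.36 M in high light, 10.11 to 11.16 M in heat and 10.42 to 15.13 M in the combination. For the libraries labelled wrky48 the ranges were 10.99 to 11.47 M, 17.85 to 20.53 M, 9.22 to 14.84 M and 10.25 to 10.48 M in the same order. The sum of normalized counts was 15.99 ± 0.0416 M (SD, n = 3) in the wild type combination and 11.08 ± 0.0751 M in the combination libraries labelled wrky48. Changes are log2 fold changes ± SE from limma with n = 3 libraries per group. List p-values are from camera, and rescaled values come from the same fit after every library was set to the same total.

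WRKY48 (AT5G49520), the gene carrying the insertion, was not lower in the libraries labelled wrky48 in 3 of the 4 conditions. In control its normalized count was 111.4 ± 12 (SD, n = 3) in these libraries and 61.5 ± 12.9 in wild type. Under heat it was 30.9 ± 5.4 against 7.4 ± 5.1, and under the combination 46.6 ± 2.6 against 10.1 ± 4.6. Under high light it was lower, at 22.7 ± 1.5 against 67.7 ± 1.9. In limma the log2 difference was 0.87 ± 0.3 in control (adjusted p = 0.06) and -1.54 ± 0.3 in high light (adjusted p = 0.00012). It was 2.08 ± 0.3 in heat (adjusted p = 1.7e-06) and 2.18 ± 0.3 in the combination (adjusted p = 8.2e-08). A two-sided exact permutation test gave p = 0.1 in each condition, the smallest value that 3 libraries against 3 allow. The groups are therefore called libraries labelled wrky48, and every direction between genotypes rests on those labels.

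**Figure D1:**
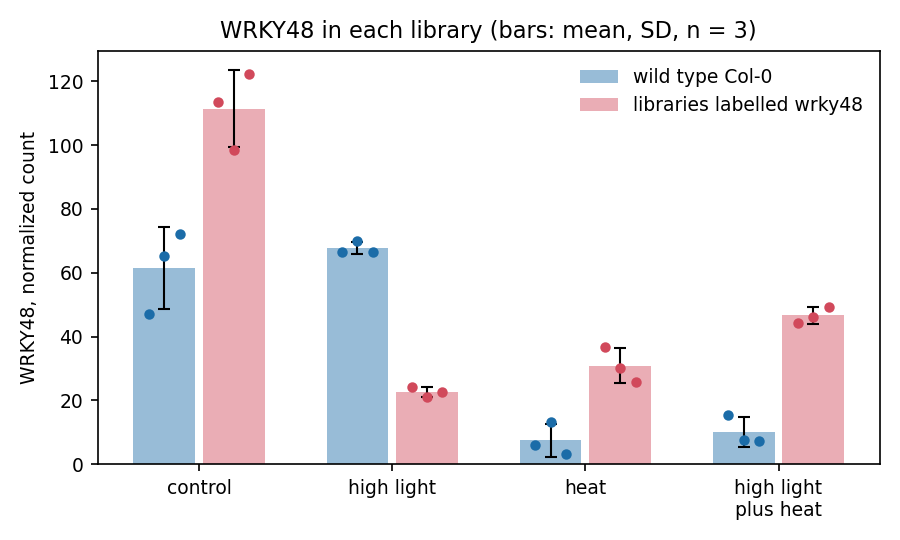
Normalized count of WRKY48 in each library by condition, with points for libraries, bars for means and error bars for the SD (n = 3). The libraries labelled wrky48 lie above wild type in control, heat and the combination, and below it in high light, where the means were 22.7 and 67.7.

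High light raised flavonoid and heat shock transcripts and lowered light-harvesting transcripts in wild type. ELIP1 (AT3G22840), an early light-induced protein of the thylakoid, rose by 10.47 ± 0.2, from 8.231 ± 0.96 normalized counts (SD, n = 3) to 13020 ± 383. ELIP2 rose by 7.24 ± 0.29, and the flavonol synthase gene FLS1 by 7.19 ± 0.14. UF3GT, an anthocyanin glycosyltransferase, rose by 7.02 ± 0.46, AT5MAT by 6.75 ± 0.54 and DFR, encoding dihydroflavonol reductase, by 6.68 ± 0.51. LTP4, a lipid transfer protein gene, had 0 reads in the wild type controls and was at least 333-fold higher under high light. ASN1, an asparagine synthetase gene, fell by 8.8 ± 0.32. LHB1B1, a light-harvesting chlorophyll protein, fell by 7.97 ± 0.04, from 33000 ± 407 counts to 130.8 ± 12.9. PORA, a protochlorophyllide reductase, fell by 7.69 ± 0.31, BXL1 fell by 7.69 ± 0.22 and TPS8 fell by 7.15 ± 0.14. DIN10 fell by 6.78 ± 0.1, GASA6 fell by 6.52 ± 0.16 and EXLA1 fell by 6.16 ± 0.16.

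Flavonoid and anthocyanin genes rose in 23 of 23 cases (the same adjusted over the list alone, median 5.77, or 5.72 with members at 0 reads at their bound, adjusted p = 2.1e-19). Heat shock proteins and chaperones rose in 23 of 24 cases and fell in 1 (the same adjusted over the list alone, median 5.03, adjusted p = 2e-19). Among them HSP17.6C rose by 8.48 ± 0.14, HSP23.6-MITO by 7.92 ± 0.15 and HSP17.6II by 7.83 ± 0.2. Light-harvesting genes fell in 19 of 21 cases and rose in 2 (the same adjusted over the list alone, median -2.42, adjusted p = 6.4e-21). LHCB2.3 fell by 5.9 ± 0.06 and LHCB4.2 fell by 4.03 ± 0.03, while LHCB4.3 rose by 3.94 ± 0.08. Jasmonate synthesis genes fell in 10 of 14 cases and rose in 1 (the same adjusted over the list alone, median -1.06, adjusted p = 2.5e-05). The allene oxide cyclase gene AOC1 fell by 4.03 ± 0.18. Genes of the unfolded protein response fell in 12 of 17 cases and rose in 2 (13 and 2 adjusted over the list alone, median -0.5, adjusted p = 4e-04). UTR1 fell by 1.6 ± 0.08 and ATERDJ3A rose by 1 ± 0.14.

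Antioxidant enzyme genes rose in 16 of 27 cases and fell in 7 (the same adjusted over the list alone, median 0.37, adjusted p = 0.00051). GPX7 rose by 3.68 ± 0.29 and the catalase gene CAT3 fell by 1.77 ± 0.03. Reactive oxygen markers rose in 8 of 12 cases and fell in 1 (the same adjusted over the list alone, median 1.8, adjusted p = 0.0014). AGC2-1 rose by 4.5 ± 0.47 and UPOX by 3.43 ± 0.18. Heat shock factor genes rose in 9 of 18 cases and fell in 2 (the same adjusted over the list alone, median 0.74, or 0.52 with members at 0 reads at their bound, adjusted p = 0.038, adjusted p = 0.094 with an estimated correlation, adjusted p = 0.076 after rescaling). HSFA2 rose by 5.28 ± 0.2. Phloem markers fell in 7 of 10 cases and rose in 1 (7 and 2 adjusted over the list alone, median -0.49, adjusted p = 0.009, adjusted p = 0.18 with an estimated correlation). In all 13273 of 20915 genes were called, 6802 higher and 6471 lower, of which 2411 and 2394 by at least 2-fold. After rescaling to equal totals the split was 8702 higher and 4945 lower, and the median of all genes was 0.183. Wild type high light library 2 stood further from its repeats (mean chi-square of reads per gene 5.261 and 3.829) than these from each other (1.753). Its share of plastid-encoded reads was 0.1148%, against 0.0164% and 0.0134% in the repeats.

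Heat alone raised heat shock transcripts and lowered salicylic acid and jasmonate synthesis transcripts in wild type. ATHSP22.0, a small heat shock protein, rose by 8.73 ± 0.12, HSP18.2 by 8.01 ± 0.08 and HSP17.6C by 7.45 ± 0.14. HSP23.6-MITO rose by 6.33 ± 0.15, HSP17.4 by 5.97 ± 0.11 and the co-chaperone gene Hop3 by 5.41 ± 0.15. CYP81F2, a cytochrome P450 gene of indole glucosinolate modification, had 1031 reads over the controls and 1 read under heat. The ratio was 924 (95% counting interval 165 to 36500). PHI-1 fell by 7.3 ± 0.32, the dehydrin gene LTI30 fell by 6.36 ± 0.19 and the pathogenesis-related gene PR1 fell by 6.32 ± 0.56. TCH4, a xyloglucan endotransglucosylase, fell by 6.27 ± 0.09 and EXLA2 fell by 6.18 ± 0.23.

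Heat shock proteins rose in 22 of 24 cases and fell in 2 (the same adjusted over the list alone, median 4.14, adjusted p = 7e-17). Genes of the unfolded protein response rose in 14 of 17 cases and fell in 3 (the same adjusted over the list alone, median 1.24, adjusted p = 2e-08). ATERDJ3A rose by 2.63 ± 0.14 and the chaperone gene BIP2 by 1.78 ± 0.03. Jasmonate synthesis genes fell in 13 of 14 cases (the same adjusted over the list alone, median -1.39, adjusted p = 7.5e-07). AOC3 fell by 3.47 ± 0.23 and LOX4 fell by 3.14 ± 0.18. Salicylic acid and pathogenesis genes fell in 19 of 21 cases and rose in 1 (20 and 1 adjusted over the list alone, median -1.58, adjusted p = 7.5e-06). PR5 fell by 5.39 ± 0.09 and the glucanase gene BGL2 fell by 3.66 ± 0.1. Other WRKY factor genes fell in 28 of 40 cases and rose in 1 (the same adjusted over the list alone, median -1.11, adjusted p = 0.00033). WRKY18 fell by 4.57 ± 0.11.

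Jasmonate response genes, not called as a list, fell in 11 of 21 cases and rose in 4 (the same adjusted over the list alone, median -0.49, adjusted p = 0.14). Reactive oxygen markers fell in 9 of 12 cases and rose in 2 (the same adjusted over the list alone, median -1.23, adjusted p = 0.013). BCB fell by 4.31 ± 0.07 and UPOX rose by 1.75 ± 0.18. Circadian clock genes rose in 15 of 21 cases and fell in 5 (the same adjusted over the list alone, median 0.55, adjusted p = 0.016). LHY, a morning-phased clock factor, fell by 3.95 ± 0.39. Light-harvesting genes rose in 14 of 21 cases and fell in 6 (the same adjusted over the list alone, median 0.16, adjusted p = 0.036, adjusted p = 0.38 with an estimated correlation). Heat shock factor genes rose in 10 of 18 cases and fell in 1 (the same adjusted over the list alone, median 0.66, adjusted p = 0.048, adjusted p = 0.11 with an estimated correlation, adjusted p = 0.066 after rescaling). HSFA2 rose by 3.29 ± 0.2. Among 14328 called genes, 6887 were higher and 7441 lower, 2412 and 2854 by at least 2-fold. The mean normalized totals were 12.1 M under heat and 12.77 M in control. Rescaling to equal totals therefore moves all genes up under heat, so the balance of higher and lower rests on the scaling.

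The combination of high light and heat gave the largest heat shock transcript levels among the 4 wild type groups. HSP17.6C rose from 2.17 ± 1.29 normalized counts (SD, n = 3) in control to 92050 ± 1810, a change of 14.91 ± 0.14. ATHSP22.0 rose by 14.32 ± 0.12, HSP18.2 by 13.28 ± 0.08, HSP17.8 by 13.18 ± 0.16 and HSP23.6-MITO by 12.37 ± 0.15. HSP21, a chloroplast small heat shock protein, had 1 read in control and 56591 under the combination. The ratio was 72300 (95% counting interval 13000 to 2860000). The ascorbate peroxidase gene APX2 and LTP4 had 0 control reads and were at least 3900-fold and at least 13200-fold higher. CYP81F2 fell by 7.67 ± 0.46, PHI-1 fell by 6.7 ± 0.32, PMT6 fell by 6.47 ± 0.35 and BGL2 fell by 6.41 ± 0.1. PR1 went from 739 reads to 2, a ratio of 289 (95% counting interval 79.7 to 2390). The receptor-like kinase gene CRK7 went from 262 reads to 0 and was at least 68.3-fold lower.

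Heat shock proteins rose in 24 of 24 cases (the same adjusted over the list alone, median 9.69, unmoved by setting members at 0 reads to their bound, adjusted p = 8.1e-22). This list held 5.52% ± 0.04 (SD, n = 3) of the normalized total, against 0.0242% ± 0.00073 in control. Genes of the unfolded protein response rose in 16 of 17 cases and fell in 1 (the same adjusted over the list alone, median 1.86, adjusted p = 7.7e-11). ATERDJ3A rose by 6.05 ± 0.14 and BIP2 by 3.75 ± 0.03. Antioxidant enzyme genes rose in 20 of 27 cases and fell in 5 (the same adjusted over the list alone, median 0.72, adjusted p = 0.00013, median 0.39 after rescaling). CAT2, a catalase gene, rose by 3.47 ± 0.03 and the superoxide dismutase gene CSD2 fell by 1.86 ± 0.04. Photoprotection and photosystem II repair genes rose in 14 of 19 cases and fell in 4 (the same adjusted over the list alone, median 0.77, adjusted p = 0.00043, median 0.44 after rescaling). ELIP1 rose by 9.86 ± 0.2 and FTSH8 by 3.73 ± 0.04. Heat shock factor genes rose in 12 of 18 cases and fell in 3 (the same adjusted over the list alone, median 1.85, adjusted p = 0.0029). HSFA2 rose by 10.71 ± 0.2.

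Salicylic acid and pathogenesis genes fell in 20 of 21 cases (the same adjusted over the list alone, median -2.61, adjusted p = 2.4e-06). The remaining WRKY genes fell in 30 of 40 cases and rose in 2 (the same adjusted over the list alone, median -1.48, adjusted p = 0.00027). Jasmonate synthesis genes fell in 11 of 14 cases and rose in 2 (the same adjusted over the list alone, median -1.84, adjusted p = 0.0024). AOC1 fell by 2.83 ± 0.18 and AOC3 fell by 2.57 ± 0.23. Flavonoid genes rose in 14 of 23 cases and fell in 5 (the same adjusted over the list alone, median 0.76, adjusted p = 0.03, median 0.43 after rescaling). The anthocyanin regulator MYB75 rose by 4.63 ± 0.14. Abscisic acid genes rose in 20 of 33 cases and fell in 10 (the same adjusted over the list alone, median 0.86, adjusted p = 0.021, adjusted p = 0.064 with an estimated correlation, median 0.53 after rescaling). HAI1, a protein phosphatase gene, rose by 5.62 ± 0.08. Clock genes rose in 14 of 21 cases and fell in 5 (the same adjusted over the list alone, median 0.78, adjusted p = 0.028, adjusted p = 0.067 with an estimated correlation, median 0.45 after rescaling). CCA1 rose by 4.18 ± 0.08 and LHY by 3.8 ± 0.39.

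Several lists were not called under the combination. Senescence genes rose in 8 of 11 cases and fell in 2 (the same adjusted over the list alone, median 1.03, adjusted p = 0.088, adjusted p = 0.039 after rescaling). Jasmonate response genes fell in 11 of 21 cases and rose in 7 (the same adjusted over the list alone, median -0.46, adjusted p = 0.36, median -1.01 after rescaling). Calvin cycle genes rose in 8 of 16 cases and fell in 7 (the same adjusted over the list alone, median 0.09, adjusted p = 0.77, median -0.23 after rescaling). Guard cell markers fell in 6 of 8 cases and rose in 1 (the same adjusted over the list alone, median -1.1, adjusted p = 0.1). Epidermis markers rose in 4 of 8 cases and fell in 3 (5 and 3 adjusted over the list alone, median 0.3, adjusted p = 0.53, median -0.03 after rescaling). Dividing cell markers fell in 6 of 9 cases and rose in 1 (the same adjusted over the list alone, median -1.46, adjusted p = 0.19). The share of mitochondrion-encoded reads was 0.36% ± 0.0394 (SD, n = 3) under the combination, 0.0596% ± 0.0008 under heat and 0.0056% ± 0.0026 in control. In wild type 16584 genes were called under the combination, 8186 higher and 8398 lower, 3945 and 4741 by at least 2-fold. After rescaling the split was 6042 higher and 10678 lower, and the median of all genes was -0.343.

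**Figure D2:**
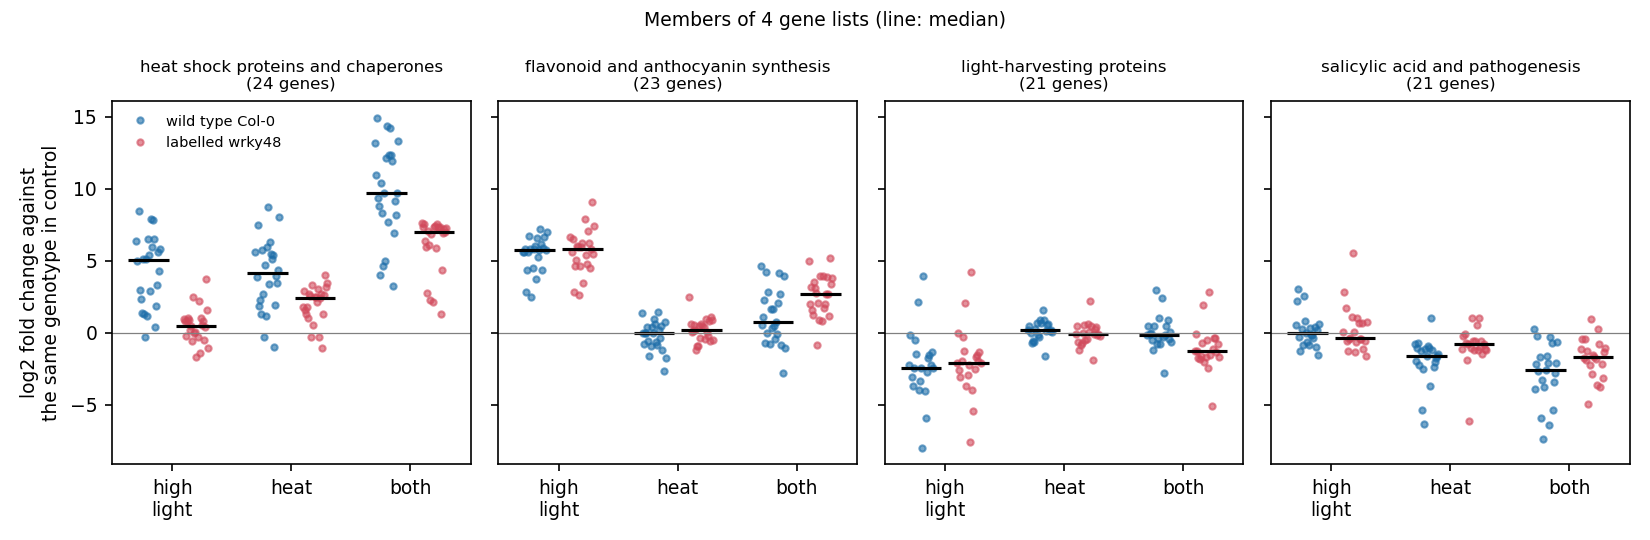
Log2 fold change against the control of the same genotype for the members of 4 gene lists under high light, heat and both, with points for genes and lines for medians. The wild type median of the heat shock list is 9.69 under the combination, and that of the flavonoid list 5.77 under high light against 0.76 under the combination.

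The combined response departed from the sum of the single responses in wild type for light-harvesting, unfolded protein response and flavonoid genes, among others. PORA lay 8.22 ± 0.44 above the sum, RAS1 8.08 ± 0.3, LHY 7.98 ± 0.55 and EXLA2 7.23 ± 0.32. ERD5, a proline dehydrogenase gene, lay 6.68 ± 0.24 above it and ASN1 6.66 ± 0.45. TT7, a flavonoid hydroxylase gene, lay at -7.23 ± 0.35 relative to the sum, LDOX at -6.39 ± 0.39 and UF3GT at -6.33 ± 0.65. IPMI1 lay at -5.61 ± 0.22 and GSTF12 at -5.56 ± 0.43. Of all genes, 14010 departed from the sum, 7363 above and 6647 below. Rescaling gave 3879 above and 11229 below, with a median of all genes of -0.528.

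Flavonoid genes lay below the sum in 23 of 23 cases (the same adjusted over the list alone, median -3.9, adjusted p = 3.4e-13). Light-harvesting genes lay above the sum in 17 of 21 cases and lay below it in 1 (the same adjusted over the list alone, median 1.97, adjusted p = 3.9e-18). LHB1B1 lay 6.51 ± 0.05 above the sum. Genes of the unfolded protein response lay above the sum in 16 of 17 cases (the same adjusted over the list alone, median 1.37, adjusted p = 1.3e-11, median 0.8 after rescaling). UTR1 lay 3.57 ± 0.12 above it. Jasmonate synthesis genes lay above the sum in 13 of 14 cases (the same adjusted over the list alone, median 0.8, adjusted p = 9.8e-06, median 0.25 after rescaling). Heat shock proteins lay above the sum in 14 of 24 cases and lay below it in 6 (14 and 7 adjusted over the list alone, median 1.27, adjusted p = 0.007, median 0.71 after rescaling). BAG6 lay 5.15 ± 0.11 above it. Lying below this log2 sum does not mean fewer counts than the single stresses add up to. HSP23.6-MITO rose by 7.92 under high light, 6.33 under heat and 12.37 under the combination in wild type. Its means were 1677.6, 556.9 and 36661.7 normalized counts in the same order. Abscisic acid genes lay above the sum in 19 of 33 cases and lay below it in 7 (20 and 7 adjusted over the list alone, median 0.6, adjusted p = 0.0032, median 0.1 after rescaling). Photoprotection genes lay above the sum in 11 of 19 cases and lay below it in 3 (the same adjusted over the list alone, median 0.4, adjusted p = 0.013, adjusted p = 0.065 with an estimated correlation, median -0.17 after rescaling, adjusted p = 0.44 after rescaling). Epidermis markers lay above the sum in 6 of 8 cases and lay below it in 1 (the same adjusted over the list alone, median 0.51, adjusted p = 0.048, adjusted p = 0.14 with an estimated correlation, median -0.06 after rescaling, adjusted p = 0.24 after rescaling). Clock genes were not called as a list and lay above the sum in 12 of 21 cases and lay below it in 6 (13 and 6 adjusted over the list alone, median 0.48, adjusted p = 0.51, median -0.08 after rescaling).

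A set of genes separated the combination from control, high light and heat at once. Hsp70b was higher than in each of the other 3 wild type groups, with a smallest log2 difference of 8.1. That smallest difference was 6.83 for HSP17.8, 6.43 for HSP17.6C and 6.41 for the disaggregase gene HSP101. It was 5.75 for the microRNA gene MIR398b and 5.62 for HSP17.4. IPMI1 was lower than in each of them, with a smallest difference of -4.7. The histone gene HTA4 followed with -4.2, GER3 with -3.63, ACD6 with -3.56 and the aliphatic glucosinolate gene CYP79F1 with -3.53. In all 8996 genes met this rule, 4712 higher and 4284 lower, and after rescaling 2521 higher and 7317 lower.

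The libraries labelled wrky48 also responded to each stress. Under high light ELIP1 rose by 9.64 ± 0.2, LDOX by 7.88 ± 0.27, MYB75 by 6.67 ± 0.14 and TT4, encoding chalcone synthase, by 6.25 ± 0.05. ASN1 fell by 9.23 ± 0.32 and LHB1B1 fell by 7.58 ± 0.04. Under heat GolS2, a galactinol synthase gene, rose by 4.7 ± 0.1, HAI2 by 4.41 ± 0.2 and TIN1 by 4.28 ± 0.15. PHI-1 fell by 7.77 ± 0.32, GSTF6 fell by 6.71 ± 0.07 and PR5 fell by 6.15 ± 0.09. Under the combination APX2 rose by 7.76 ± 0.29, HSP17.8 by 7.62 ± 0.16 and HSP17.6C by 7.52 ± 0.14. With 0.57% of the level of the combination libraries labelled wrky48 subtracted from the controls of that genotype, an alternative chosen after the data had been seen, the 3 rises were 9.86, 13.02 and 13.6, that of ELIP1 under high light was 11.28 and that of HAI2 under heat 5.29. The subtraction left almost no counts in those controls for genes such as HSP17.8 and HSP17.6C. Such sizes rest on the pseudocount and are not measured folds. PHI-1 fell by 6.99 ± 0.32, PAD3, a camalexin synthesis gene, fell by 6.33 ± 0.4 and PORA fell by 5.83 ± 0.31. Called genes numbered 13104 under high light, 6852 higher and 6252 lower. They numbered 14213 under heat (6911 higher, 7302 lower) and 15818 under the combination (7939 higher, 7879 lower). Rescaled splits were 9137 higher and 5512 lower under heat, and 10139 and 6126 under the combination. The medians of all genes were then 0.138, 0.206 and 0.265 under high light, heat and the combination.

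In control, heat shock transcripts were higher, and jasmonate and salicylic acid transcripts lower, in the libraries labelled wrky48 than in wild type. ATHSP22.0 was higher by 6.16 ± 0.12, HSP17.6C by 5.75 ± 0.14, HSP18.2 by 4.84 ± 0.08 and HSP17.4 by 3.47 ± 0.11. HSP17.6B was higher by 2.69 ± 0.07, LTP3 by 1.87 ± 0.12 and ROF2 by 0.97 ± 0.08. LTP4 had 0 reads in wild type and 171 in these libraries, at least 64.9-fold higher. PR1 had 739 reads in wild type and 3 in the labelled libraries, a ratio of 216 (95% counting interval 73.7 to 1050). MRD1 differed by -6.01 ± 0.39, AIG1 by -4.7 ± 0.41, EARLI1 by -4.12 ± 0.48 and SAG13 by -3.38 ± 0.22. The extensin gene EXT3 differed by -3.02 ± 0.19 and WAK3, a wall-associated kinase gene, by -2.83 ± 0.29.

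Heat shock proteins were higher in 15 of 24 cases and were lower in 1 (18 and 1 adjusted over the list alone, median 0.92, or 0.8 with members at 0 reads at their bound, adjusted p = 1.4e-41). Genes with at least 2000 normalized counts in the combination libraries labelled wrky48, and at most 0.1% of that in wild type controls, numbered 11. In these genes the excess was 0.445 to 0.762% of the level in the combination libraries labelled wrky48. After 0.57% of that level was subtracted, an alternative chosen after the data had been seen, 4 of the heat shock proteins were higher and 9 lower, with a median of -0.28. HSP17.6C, HSP17.4 and ATHSP22.0 were then not called, and ROF2 was lower, at -0.84. Where the share of a gene was below 0.57%, the subtraction took away more than its excess, so lower calls can follow from it alone. Jasmonate synthesis genes were lower in 11 of 14 cases (12 adjusted over the list alone, median -0.46, adjusted p = 3.3e-23). OPR3 differed by -0.86 ± 0.06. Jasmonate response genes were lower in 8 of 21 cases and were higher in 1 (10 and 1 adjusted over the list alone, median -0.29, adjusted p = 1.6e-10). The storage protein genes VSP1 and VSP2 differed by -1.39 ± 0.1 and -1.35 ± 0.06. Salicylic acid and pathogenesis genes were lower in 11 of 21 cases (13 adjusted over the list alone, median -0.42, adjusted p = 1.3e-11). BGL2 differed by -2.56 ± 0.1.

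**Figure D3:**
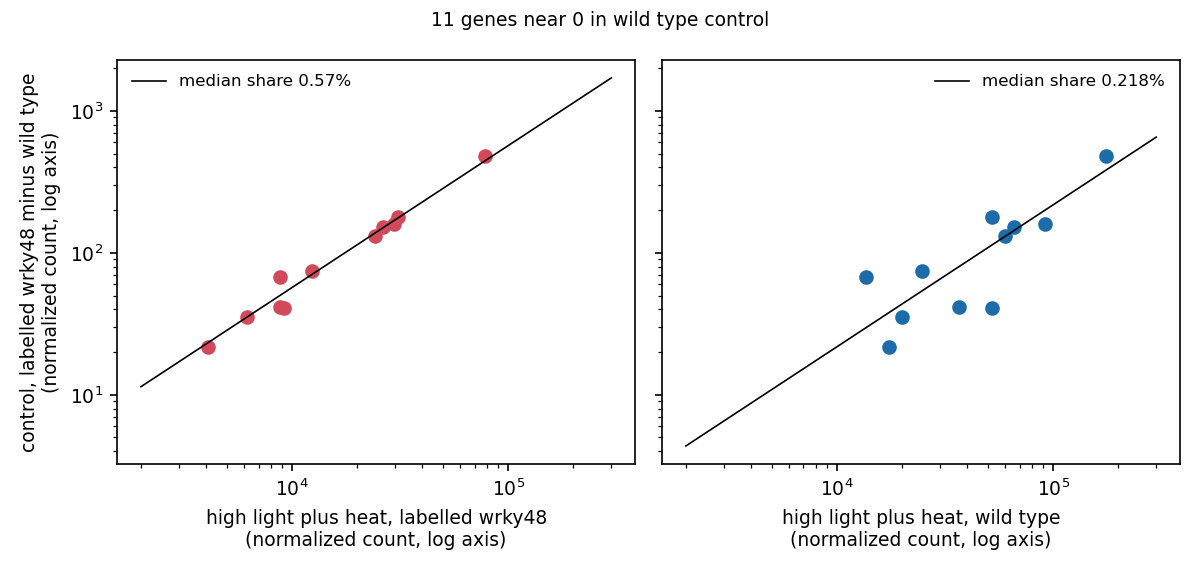
Excess of 11 genes in the control libraries labelled wrky48 over wild type controls, against their normalized count under high light plus heat in each genotype, on log axes, with a line at the median share. The share is 0.57% against the libraries labelled wrky48, where the points lie closer to the line, and 0.218% against wild type.

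Light-harvesting genes were higher in 17 of 21 cases and were lower in 1 (the same adjusted over the list alone, median 0.15, adjusted p = 6.1e-24). LHB1B1 was higher by 0.28 ± 0.04. Genes of the other WRKY factors were lower in 8 of 40 cases and were higher in 1 (8 and 2 adjusted over the list alone, median -0.17, unmoved by setting members at 0 reads to their bound, adjusted p = 0.0014). WRKY46 differed by -2.3 ± 0.2. Reactive oxygen markers were lower in 5 of 12 cases and were higher in 1 (7 and 1 adjusted over the list alone, median -0.31, adjusted p = 0.008). BAP1 differed by -1.49 ± 0.32. Senescence genes were lower in 1 of 11 cases, SAG13 (the same adjusted over the list alone, median -0.17, adjusted p = 0.03). Calvin cycle genes were higher in 6 of 16 cases and were lower in 1 (7 and 1 adjusted over the list alone, median 0.05, adjusted p = 0.00025, adjusted p = 0.1 with an estimated correlation, median 0 after rescaling, adjusted p = 0.67 after rescaling). Phloem markers were higher in 4 of 10 cases and were lower in 2 (the same adjusted over the list alone, median 0.12, adjusted p = 0.037, adjusted p = 0.28 with an estimated correlation, median 0.07 after rescaling, adjusted p = 0.084 after rescaling). In all 2106 genes were called, 1086 higher and 1020 lower, 64 and 309 by at least 2-fold. With the 0.57% subtraction, 42 genes were higher by at least 2-fold. Rescaling gave 619 higher and 1519 lower.

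Under high light, heat shock and reactive oxygen transcripts were lower and light-harvesting and Calvin cycle transcripts higher in the libraries labelled wrky48. ORA47 was higher by 3.97 ± 0.21, BT2 by 2.5 ± 0.13 and the ethylene response factor genes ERF104 and ERF5 by 2.03 ± 0.16 and 2.02 ± 0.33. JAZ6, a jasmonate repressor gene, was higher by 1.84 ± 0.11, CBF2 by 1.75 ± 0.15 and RAV1 by 1.73 ± 0.1. MYB15 differed by -5.54 ± 0.6, MRD1 by -5.43 ± 0.39, WRKY30 by -3.94 ± 0.35 and MLO12 by -3.61 ± 0.5. HSP17.6II differed by -3.49 ± 0.2, PAD3 by -3.49 ± 0.4 and HSP17.6A by -3.45 ± 0.13. In all 4558 genes were called, 2565 higher and 1993 lower, 156 and 798 by at least 2-fold. Rescaling gave 1123 higher and 3335 lower.

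Heat shock proteins were lower in 23 of 24 cases and were higher in 1 (the same adjusted over the list alone, median -2.01, adjusted p = 4.3e-45). Heat shock factor genes were lower in 4 of 18 cases (the same adjusted over the list alone, median -0.15, adjusted p = 0.008, median -0.26 after rescaling). HSFA2 differed by -1.12 ± 0.2. Reactive oxygen markers were lower in 9 of 12 cases and were higher in 1 (the same adjusted over the list alone, median -1.26, adjusted p = 5.3e-10). AGC2-1 differed by -2.54 ± 0.47 and WRKY33 by -1.99 ± 0.09. Salicylic acid and pathogenesis genes were lower in 11 of 21 cases (14 adjusted over the list alone, median -0.42, adjusted p = 4.5e-08). WRKY genes other than WRKY48 were lower in 16 of 40 cases and were higher in 2 (19 and 2 adjusted over the list alone, median -0.34, adjusted p = 7.9e-07). WRKY6 differed by -2.6 ± 0.23.

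Light-harvesting genes were higher in 18 of 21 cases (18 and 1 adjusted over the list alone, median 0.33, adjusted p = 2.5e-34). CAB2 was higher by 0.88 ± 0.02. Calvin cycle genes were higher in 16 of 16 cases (the same adjusted over the list alone, median 0.28, adjusted p = 1.4e-27, median 0.17 after rescaling). The Rubisco activase gene RCA was higher by 0.43 ± 0.02. Photoprotection genes were higher in 7 of 19 cases (10 adjusted over the list alone, median 0.11, adjusted p = 0.00072, median 0 after rescaling, adjusted p = 0.23 after rescaling). Phloem markers were higher in 9 of 10 cases (the same adjusted over the list alone, median 0.22, adjusted p = 0.00045, adjusted p = 0.079 with an estimated correlation, median 0.11 after rescaling).

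Under heat, abscisic acid transcripts were higher in the libraries labelled wrky48. DIC2, a mitochondrial dicarboxylate carrier gene, was higher by 4.14 ± 0.15, CAF1a by 3.33 ± 0.14 and CYP707A3, an abscisic acid hydroxylase gene, by 2.98 ± 0.18. The zinc finger gene STZ was higher by 2.96 ± 0.14, the ethylene synthesis gene ACS6 by 2.35 ± 0.11 and CBF1 by 2.2 ± 0.16. MRD1 differed by -6.07 ± 0.39, QQS by -3.29 ± 0.15 and RAD23C by -2.3 ± 0.08. CSD2 differed by -1.8 ± 0.04, CAX3 by -1.76 ± 0.07 and DMR6 by -1.58 ± 0.11. In all 3734 genes were called, 1294 higher and 2440 lower, 251 and 171 by at least 2-fold. Heat library 3 labelled wrky48 stood further from its repeats (mean chi-square of reads per gene 3.393 and 3.21) than these from each other (1.789). Without it 3032 genes were called. Rescaling gave 2274 higher and 1181 lower, and a fit on the groups of the comparison alone called 2381 genes.

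Abscisic acid genes were higher in 14 of 33 cases and were lower in 3 (18 and 4 adjusted over the list alone, median 0.23, or 0.21 with members at 0 reads at their bound, adjusted p = 7.3e-07). Other WRKY factor genes were higher in 10 of 40 cases and were lower in 1 (10 and 2 adjusted over the list alone, median 0.24, adjusted p = 2e-04). WRKY22 was higher by 1.52 ± 0.27. Jasmonate synthesis genes were higher in 8 of 14 cases and were lower in 1 (the same adjusted over the list alone, median 0.18, adjusted p = 0.00035). AOC3 was higher by 1.14 ± 0.23. Flavonoid genes were higher in 7 of 23 cases (8 adjusted over the list alone, median 0.17, adjusted p = 0.0017). Antioxidant enzyme genes were lower in 14 of 27 cases and were higher in 2 (16 and 2 adjusted over the list alone, median -0.13, adjusted p = 1.8e-08, median -0.05 after rescaling). CSD1 differed by -1.06 ± 0.05 and CAT2 by -0.58 ± 0.03. Light-harvesting genes were lower in 12 of 21 cases (14 and 1 adjusted over the list alone, median -0.12, adjusted p = 9e-10, median -0.03 after rescaling).

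Heat shock proteins were lower in 10 of 24 cases and were higher in 2 (12 and 2 adjusted over the list alone, median -0.23, adjusted p = 5e-04, median -0.14 after rescaling). HSP17.8 differed by -0.76 ± 0.16. Heat shock factor genes were higher in 4 of 18 cases (the same adjusted over the list alone, median 0.07, adjusted p = 0.032, adjusted p = 0.083 with an estimated correlation, median 0.16 after rescaling, adjusted p = 0.091 after rescaling). Epidermis markers were higher in 5 of 8 cases and were lower in 1 (5 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.028, adjusted p = 0.11 with an estimated correlation, median 0.26 after rescaling). PDF1 was higher by 0.82 ± 0.11. Calvin cycle genes were lower in 10 of 16 cases and were higher in 1 (the same adjusted over the list alone, median -0.06, adjusted p = 6.1e-05, adjusted p = 0.075 with an estimated correlation, median 0.02 after rescaling, adjusted p = 0.96 after rescaling). Photoprotection genes were lower in 7 of 19 cases (the same adjusted over the list alone, median -0.07, adjusted p = 0.024, adjusted p = 0.088 with an estimated correlation, median 0.02 after rescaling, adjusted p = 0.67 after rescaling).

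Under the combination, heat shock and light-harvesting transcripts were lower in the libraries labelled wrky48, and several anthocyanin genes were higher. UF3GT was higher by 4.29 ± 0.46 and LDOX by 2.88 ± 0.27. DFR had 194 reads over these 3 libraries and 3 reads over those of wild type. The peroxidase gene PRXCA was higher by 5.26 ± 0.51, GRP9 by 4.73 ± 0.54, ERF11 by 3.04 ± 0.34 and GSTF11 by 2.85 ± 0.18. MRD1 differed by -4.19 ± 0.39, QQS by -4.04 ± 0.15, RAD23C by -3.57 ± 0.08 and Hsp70b by -3.38 ± 0.1. The calmodulin-like gene TCH3 differed by -3.32 ± 0.08, ELI3-2 by -3.13 ± 0.32 and HSFA7A by -2.99 ± 0.41. In all 12644 genes were called, 5723 higher and 6921 lower, 1957 and 938 by at least 2-fold. Rescaling gave 13048 higher and 1872 lower, with 1822 genes of opposite sign, and the median of all genes was then 0.492.

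Heat shock proteins were lower in 24 of 24 cases (the same adjusted over the list alone, median -1.95, adjusted p = 1.4e-15). They held 2.96% ± 0.053 (SD, n = 3) of the normalized total, against 5.52% ± 0.04 in wild type. HSP101 differed by -2.57 ± 0.09. Light-harvesting genes were lower in 20 of 21 cases (the same adjusted over the list alone, median -1.01, adjusted p = 2.9e-23, median -0.48 after rescaling). LHCB2.3 differed by -1.98 ± 0.06. Calvin cycle genes were lower in 15 of 16 cases (the same adjusted over the list alone, median -0.58, adjusted p = 6.5e-15, median -0.05 after rescaling). Photoprotection genes were lower in 18 of 19 cases (the same adjusted over the list alone, median -0.83, adjusted p = 2.9e-12, median -0.3 after rescaling). ELIP1 differed by -1.97 ± 0.2. Antioxidant enzyme genes were lower in 23 of 27 cases (the same adjusted over the list alone, median -0.62, adjusted p = 1.2e-12, median -0.09 after rescaling). CAT2 differed by -1.29 ± 0.03.

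The remaining WRKY genes were higher in 20 of 40 cases and were lower in 3 (the same adjusted over the list alone, median 0.52, or 0.42 with members at 0 reads at their bound, adjusted p = 0.00051, median 0.95 after rescaling, adjusted p = 0.096 after rescaling). WRKY53 was higher by 2.72 ± 0.21 and WRKY6 by 2.12 ± 0.23. Flavonoid genes were higher in 12 of 23 cases and were lower in 4 (the same adjusted over the list alone, median 0.84, adjusted p = 0.0049, adjusted p = 0.059 after rescaling). Genes of the unfolded protein response were lower in 16 of 17 cases (the same adjusted over the list alone, median -0.42, adjusted p = 5.7e-07, median 0.11 after rescaling). ATERDJ3A differed by -1.65 ± 0.14. Senescence genes were lower in 8 of 11 cases and were higher in 1 (the same adjusted over the list alone, median -0.52, adjusted p = 0.011, median 0.01 after rescaling). Phloem markers were lower in 8 of 10 cases and were higher in 2 (the same adjusted over the list alone, median -0.48, adjusted p = 0.046, adjusted p = 0.3 with an estimated correlation, median 0.05 after rescaling, adjusted p = 0.67 after rescaling). The share of mitochondrion-encoded reads was 0.2509% ± 0.0296 (SD, n = 3) in the libraries labelled wrky48 and 0.36% ± 0.0394 in wild type.

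In all 4 conditions, 45 genes were called higher and 114 lower in the libraries labelled wrky48, where independent lists would share 2.3 and 3.8. Of the 566 genes called in all 4 these are 159, and 272 had 1 sign in 2 conditions and the other sign in the remaining 2. After rescaling 53 were higher and 90 lower in all 4 (2.2 and 1.2 if independent), of 410 genes called in all 4, and 85 stood 2 against 2. Independence is a low baseline where the same genes are easier to call in each condition. AT2G11405 had 0 reads in every wild type group. Its means in the libraries labelled wrky48 were 36.07, 53.36, 70.1 and 59.15 normalized counts under control, high light, heat and the combination. In control MRD1 stood at 329 ± 27.6 (SD, n = 3) in wild type and 4.335 ± 1.83 in the labelled libraries, and the ubiquitin receptor gene RAD23C at 921.6 ± 30.5 and 357.8 ± 30.2. In the same order of conditions, the log2 differences were -2.7, -1.88, -3.29 and -4.04 for QQS. They were -1.23, -1.42, -1.68 and -1.26 for GAD and -1.23, -0.86, -1.66 and -2.1 for GAD4, both encoding glutamate decarboxylase.

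The question of how wrky48 plants differ in their responses was tested as the difference of the responses between genotypes. A value above 0 is a larger rise or a smaller fall in the libraries labelled wrky48 than in wild type, or a rise against a fall, and a value below 0 is the reverse. All 3 differences share the control libraries, where the medians between genotypes were -0.46 for jasmonate synthesis, -0.29 for jasmonate response and -0.42 for salicylic acid genes. The difference was 3.81 ± 0.3 for ORA47 and 2.46 ± 0.19 for BT2 under high light. Under heat DIC2 differed by 3.75 ± 0.21 and CYP707A3 by 2.88 ± 0.26. Under the combination EXT3 differed by 5.38 ± 0.26, UF3GT by 4.85 ± 0.65 and LDOX by 4.38 ± 0.39. The response differed in 2131 genes for high light (1218 above, 913 below), 3178 for heat (1180 above, 1998 below) and 10452 for the combination (4569 above, 5883 below). Rescaling gave 828 above and 1201 below for high light, 2287 and 844 for heat, and 11938 and 1270 for the combination. The medians of all genes were then 0.117 for heat and 0.552 for the combination.

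For high light, the differences for heat shock proteins lay below 0 in 22 of 24 cases and lay above 0 in 1 (23 and 1 adjusted over the list alone, median -3.06, adjusted p = 3.7e-88). With the 0.57% subtraction from the control libraries labelled wrky48 the median was -1.26 (adjusted p = 3.4e-18). Jasmonate synthesis genes lay above 0 in 9 of 14 cases and lay below 0 in 1 (10 and 2 adjusted over the list alone, median 0.62, adjusted p = 4e-13). AOC1 fell by 4.03 ± 0.18 in wild type and fell by 1.69 ± 0.18 in the libraries labelled wrky48. Jasmonate response genes lay above 0 in 6 of 21 cases and lay below 0 in 3 (7 and 3 adjusted over the list alone, median 0.4, adjusted p = 0.00018). Between genotypes under high light itself, the lists of jasmonate synthesis (median 0.12, adjusted p = 0.39) and jasmonate response genes (median 0.15, adjusted p = 0.29) were not called. Calvin cycle genes lay above 0 in 15 of 16 cases (the same adjusted over the list alone, median 0.22, adjusted p = 1.3e-25). Light-harvesting genes lay above 0 in 13 of 21 cases (15 adjusted over the list alone, median 0.22, adjusted p = 3.9e-23). In wild type the jasmonate synthesis and light-harvesting lists fell under high light, with medians of -1.06 and -2.42. Reactive oxygen markers lay below 0 in 7 of 12 cases and lay above 0 in 2 (the same adjusted over the list alone, median -0.72, adjusted p = 1.9e-08). Photoprotection genes lay above 0 in 5 of 19 cases (8 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.007, median 0.02 after rescaling, adjusted p = 0.12 after rescaling).

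For heat, the differences for heat shock proteins lay below 0 in 17 of 24 cases and lay above 0 in 1 (the same adjusted over the list alone, median -1.3, adjusted p = 1.8e-34). With the 0.57% subtraction from the control libraries labelled wrky48 that median turned to 0.19 (adjusted p = 0.61). Jasmonate synthesis genes lay above 0 in 12 of 14 cases and lay below 0 in 1 (the same adjusted over the list alone, median 0.72, adjusted p = 3.2e-17). AOC3 fell by 3.47 ± 0.23 in wild type and fell by 1.27 ± 0.23 in the libraries labelled wrky48. Salicylic acid and pathogenesis genes lay above 0 in 6 of 21 cases and lay below 0 in 1 (10 and 1 adjusted over the list alone, median 0.49, adjusted p = 7.4e-07). BGL2 fell by 3.66 ± 0.1 and fell by 1.18 ± 0.1 in the same order. The direct comparison of genotypes under heat did not call the salicylic acid list (median 0.05, adjusted p = 0.54). The wild type medians under heat were -1.39 for jasmonate synthesis and -1.58 for salicylic acid genes. Light-harvesting genes lay below 0 in 17 of 21 cases and lay above 0 in 1 (the same adjusted over the list alone, median -0.26, adjusted p = 1.9e-24, median -0.13 after rescaling). Antioxidant enzyme genes lay below 0 in 14 of 27 cases and lay above 0 in 3 (17 and 3 adjusted over the list alone, median -0.19, adjusted p = 1.6e-07, median -0.05 after rescaling). Calvin cycle genes lay below 0 in 10 of 16 cases (11 adjusted over the list alone, median -0.11, adjusted p = 3.4e-08, median 0.03 after rescaling, adjusted p = 0.86 after rescaling). Photoprotection genes lay below 0 in 6 of 19 cases and lay above 0 in 1 (the same adjusted over the list alone, median -0.1, adjusted p = 0.013, adjusted p = 0.065 with an estimated correlation, median 0.04 after rescaling, adjusted p = 1 after rescaling).

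For the combination, the differences for heat shock proteins lay below 0 in 24 of 24 cases (the same adjusted over the list alone, median -2.94, adjusted p = 6.4e-28). The 0.57% subtraction gave a median of -1.55 (adjusted p = 2.1e-06). Light-harvesting genes lay below 0 in 20 of 21 cases and lay above 0 in 1 (the same adjusted over the list alone, median -1.16, adjusted p = 3.8e-28, median -0.57 after rescaling). Calvin cycle genes lay below 0 in 15 of 16 cases (the same adjusted over the list alone, median -0.59, adjusted p = 6.1e-18, median -0.01 after rescaling). Jasmonate synthesis genes lay above 0 in 11 of 14 cases and lay below 0 in 1 (11 and 2 adjusted over the list alone, median 0.53, adjusted p = 6.8e-05, median 1.11 after rescaling). Jasmonate response genes lay above 0 in 11 of 21 cases and lay below 0 in 3 (the same adjusted over the list alone, median 0.77, adjusted p = 0.00036, median 1.34 after rescaling). VSP1 rose by 3.21 ± 0.1 in the libraries labelled wrky48 and its change was not called in wild type (log2 -0.13, adjusted p = 0.23), a difference of 3.34 ± 0.14 (adjusted p = 1.6e-21). Salicylic acid and pathogenesis genes lay above 0 in 11 of 21 cases and lay below 0 in 1 (12 and 2 adjusted over the list alone, median 0.71, adjusted p = 0.0014, median 1.14 after rescaling). Genes of the other WRKY factors lay above 0 in 24 of 40 cases (the same adjusted over the list alone, median 0.7, adjusted p = 7.5e-06, median 1.28 after rescaling). Genes of the unfolded protein response lay below 0 in 13 of 17 cases (14 adjusted over the list alone, median -0.31, adjusted p = 1.7e-05, median 0.27 after rescaling, adjusted p = 0.38 after rescaling). Phloem markers lay below 0 in 8 of 10 cases and lay above 0 in 1 (9 and 1 adjusted over the list alone, median -0.58, adjusted p = 0.011, adjusted p = 0.19 with an estimated correlation, median 0 after rescaling, adjusted p = 0.33 after rescaling). Between genotypes under the combination itself, the lists of jasmonate synthesis (median 0.02, adjusted p = 0.51), jasmonate response (median 0.27, adjusted p = 0.068) and salicylic acid genes (median 0.06, adjusted p = 0.44) were not called. The wild type medians under the combination were -0.12 for light-harvesting, 0.09 for Calvin cycle, -1.84 for jasmonate synthesis, -2.61 for salicylic acid, -1.48 for WRKY and -0.21 for phloem genes. Reads of near-identical family members, such as light-harvesting and small heat shock genes, can be split between copies by the counting, and strand use was not stated, so single members of these families are uncertain.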

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

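Tests of the control heat shock excess, of the WRKY48 level, of genotypes exchanged within conditions, of 1 wrong factor between genotypes and of the rescaled share of differences against the wild type response were chosen after those results were seen. The responses of the 2 genotypes differed by a direct test of the difference, in 2131 genes for high light, 3178 for heat and 10452 for the combination. WRKY48 passed the same limma test, its log2 response in the libraries labelled wrky48 differing by -2.4 (adjusted p = 7.3e-05) for high light, 1.22 (adjusted p = 0.046) for heat and 1.31 (adjusted p = 0.0095) for the combination. The difference for heat lost its call in 9 of the 12 fits without 1 library, where it ranged from 0.81 to 1.67, and also with a pseudocount of 5 (log2 difference 0.77) and without the filter. The adjusted p in the fits that lost the call ran from 0.057 to 0.19. It was called without wild type control library 1, without wild type heat library 2, and without heat library 3 of those labelled wrky48.

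Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many called genes. The real count and the highest of the other splits were 13273 and 0 for high light, 14328 and 0 for heat and 16584 and 0 for the combination in wild type. In the libraries labelled wrky48 they were 13104 and 1, 14213 and 1, and 15818 and 1. Between genotypes they were 2106 and 4 in control, 4558 and 1 in high light, 3734 and 3 in heat and 12644 and 11 in the combination. For the departure from the sum of the single responses (14010 genes, highest other 10137) and for the genes that set the combination apart (8996, highest other 3382), 1 of 100 splits was as large, the real one. These splits also mix control and stressed libraries and ask whether the wild type groups differ at all. They therefore cannot decide on chance for a departure from the sum or for the combination alone. For the differences between genotypes in the response to high light, heat and the combination, 9, 10 and 9 of 100 splits were as large as 2131, 3178 and 10452, and chance is not excluded by these splits. The highest other counts were 10357, 15491 and 13582, and counts several times the real one for high light and heat point to the structure of the samples, since these splits mix control and stressed libraries. With libraries exchanged between genotypes only within a condition, 5 of 100 splits were as large for high light (highest other 4772). The other 4 each kept or exchanged the genotypes of 1 condition as a whole and hold its genotype difference, so they point to the structure of the samples, and for high light chance is left open. Of 83 splits that mixed the genotypes in both conditions, a division made after the counts were seen, 0 were as large (highest 2). For heat (highest other 2706) and the combination (highest other 9625) 1 of 100 was as large, the real one. Of the other splits, 80 for heat and 84 for the combination mixed the genotypes in both conditions and called at most 2 and 1 genes. The highest counts came from splits that kept or exchanged a condition as a whole. Exchange within conditions asks whether the genotypes differ at all, so it cannot decide on chance for a difference of responses.

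Heat shock genes were higher in the control libraries labelled wrky48 than in wild type controls. For 11 genes this excess scaled with their level in the heat libraries labelled wrky48 with an SD of the log2 share of 1.12. In these genes this argues against a response to heat alone. With the combination libraries labelled wrky48 the SD was 0.21. The 11 genes were chosen by their level in those combination libraries and in wild type controls, so both SDs cover only genes high under the combination. Reads carried over from the combination libraries labelled wrky48 are a candidate explanation, at a median share of 0.57%. Such a carry-over would have to reach all 3 control libraries at a similar share, with medians of 0.605, 0.521 and 0.579% in libraries 1, 2 and 3. After that share was subtracted, LTP4 was still higher by 3.55 (adjusted p = 1.9e-08 in limma) and HSP18.2 by 1.52 (adjusted p = 2.7e-06). LTP4 had 0 reads in the wild type controls, so the size of its difference rests on the pseudocount. HSP17.8 was lower, at -2.35 (adjusted p = 1.1e-12 in limma), but its own share was only 0.445%. Subtracting 0.57% left it almost no counts in these controls, so that size and p-value rest on the pseudocount. For LTP4 and HSP18.2, 1 constant share did not remove the difference. A weak response of the control plants in the proportions of the combined stress was not tested and stays open.

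WRKY48 reads were not lower in the libraries labelled wrky48 in control, heat and the combination. Labels exchanged in high light alone would give most genes called in all 4 conditions the opposite sign there. Of 566 such genes, 34 had the opposite sign in high light alone, against 159 with 1 sign throughout. Another 272 stood 2 against 2. Of 18 genes with a difference of at least 2-fold in all 4 conditions, 15 had 1 sign throughout and 0 the opposite sign in high light alone. Of these 18, 1 was opposite in heat alone, 1 in the combination alone, and 1 stood 2 against 2. Scaling is argued against by the log2 difference under heat, 2.17 ± 0.3 (SE) with every library at the same total. An exchange of the genotype labels in all 4 conditions would leave high light unexplained, where WRKY48 was lower (log2 difference -1.54), and was not tested further. A transcript that remains despite the insertion is a biological explanation and was not tested. It does not by itself say why the level was higher under heat and the combination and lower under high light. Both explanations stay open.

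Under the combination 12644 genes differed between genotypes, and 14920 did with every library at the same total, which moves all genes together and so raises the number by itself. No constant log2 shift from -2 to 2 between the genotypes left fewer than 12605 genes called, which argues against 1 wrong factor as the cause of the number, although the directions depend on scaling (13048 higher and 1872 lower, with 1822 called genes of opposite sign, at equal totals). A response of 1 smaller size in the libraries labelled wrky48 would place nearly all 2-fold differences against the wild type response, and 85.7% did (2046 of 2388, exact 95% interval 84.2 to 87.1). After rescaling the share was 89% (3652 of 4104), but 188 of 570 genes that rose in wild type were then lower, against 634 of 783 as deposited. Both shares lie between the bounds set before the data were examined, and both rest on wild type combination libraries used in each difference, which alone may raise them, so a smaller response and other differences cannot be told apart.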

How the results depend on the processing

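The carry-over subtraction, the rescaled share of differences against the wild type response and the rescaled tallies of signs between conditions were added after the data had been seen, and the other alternatives were planned before. Counts of called genes stayed within 1.5 times under every alternative run, except for the genotypes under heat in a fit on the groups of the contrast, with 2381 genes against 3734 (the cause was not tested). Without 1 library the counts ranged over 12454 to 12574, 13564 to 13677 and 16064 to 16168 for wild type under high light, heat and the combination, and 12287 to 12503, 13499 to 13571 and 15270 to 15365 for the libraries labelled wrky48. Between genotypes they ranged over 1638 to 1783 in control, 3765 to 3990 in high light, 3032 to 3239 in heat and 11759 to 12004 in the combination. The differences of responses ranged over 1784 to 1949, 2807 to 2987 and 9870 to 10153, the departure from the sum over 13559 to 13759, and the combination-specific genes over 8676 to 8890. edgeR and DESeq2 called 2255 and 2031 genes between genotypes in control, 5863 and 5195 in high light, 3860 and 3578 in heat and 12477 and 12051 in the combination.

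For 649 pairs of a named gene and a contrast, the direction and the call were the same in 643 with a pseudocount of 0.5, 645 with 5, 633 without the filter, 637 with edgeR, 639 with DESeq2 and 623 after rescaling. Without 1 library they were the same in 5000 of 5142 values, and the other 142 kept the direction and lost the call. Rescaling ended the call of 24 pairs and took 2 to 0 or beyond, SULTR2;1 under the combination (log2 difference 0) and PKT3 in the difference of combined responses (0.08). Rescaling also changed the call of 24 of 220 list tests and the sign of 10 called medians. By construction it raises the combination libraries labelled wrky48, whose totals were lower, against those of wild type. WRKY48 was at 0.81, -1.65, 2.17 and 2.67 in control, high light, heat and the combination after rescaling. Its difference in control passed the threshold with a pseudocount of 5 (0.82), edgeR (0.86) and DESeq2 (0.87).

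The carry-over subtraction, by its construction, lowers in the control libraries labelled wrky48 the genes that are high under the combination. In control HSP17.6C went to -0.34, HSP17.4 to -0.75 and ROF2 to -0.84. In the difference of heat responses HSP17.8 went to 1.58, HSP17.6C to 0.25, ELIP1 to 0.67, HSP17.4 to 0.7 and HSP23.6-MITO to 1.06. HSP17.8, with a share of 0.445%, and HSP17.6C were left almost no counts in these controls, so their sizes rest on the pseudocount. Another 13 pairs lost their call, among them HSP17.8 (-0.02), HSP17.4 (-2.22) and HSP23.6-MITO (-1.35) in the difference of high light responses. The subtraction changed the call of 6 of 220 list tests and the sign of 2 called medians. The heat shock list stayed called and negative in the difference of high light responses (median -1.26, adjusted p = 3.4e-18) and of combined responses (median -1.55, adjusted p = 2.1e-06). Counts were 2078 between genotypes in control and 2105, 3064 and 10401 for the differences of responses.

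The labels give the repeats numbers and do not say that equal numbers share a day. After group means were removed, the 84 pairs of libraries with the same number had a median correlation of -0.00105 (range -0.0441 to 0.0332), so the numbers show no pairing. With the number as a block, 2062, 4566, 3687 and 12605 genes were called between genotypes in control, high light, heat and the combination, and 0 of 220 list calls changed with the preset correlation and 3 with the estimated one. The WRKY48 difference of heat responses had the same size (1.22) and lost its call in the block fit.

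Recovery of small changes was limited in simulated libraries, with 3 per group at these depths, and depth was not varied, so its part is not known. There limma recovered 74% of genes changed by 0.5 (log2) between genotypes under the combination and 44% in the difference of combined responses. The simulation changed few of its 19842 genes and built every group from wild type control levels. In the real comparisons 60.5% and 50% of genes were called. With more genes changed the adjusted p is less strict, so these shares do not carry over directly.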

Other observations

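The tests in this part were chosen after the data had been seen, except those of the gene lists. Values above 0 in a difference of responses are larger rises or smaller falls in the libraries labelled wrky48 than in wild type, or a rise against a fall, and values below 0 the reverse. For heat, jasmonate response genes lay above 0 in 9 of 21 cases (10 adjusted over the list alone, median 0.49, adjusted p = 3e-07). WRKY genes besides WRKY48 lay above 0 in 12 of 40 cases (13 adjusted over the list alone, median 0.45, adjusted p = 8.5e-07). Abscisic acid genes lay above 0 in 13 of 33 cases and lay below 0 in 4 (14 and 4 adjusted over the list alone, median 0.3, adjusted p = 8.4e-05). Flavonoid genes lay above 0 in 6 of 23 cases (8 adjusted over the list alone, median 0.19, adjusted p = 0.00051, median 0.33 after rescaling). Reactive oxygen markers lay above 0 in 6 of 12 cases and lay below 0 in 2 (8 and 2 adjusted over the list alone, median 0.89, adjusted p = 0.0014). For the combination, photoprotection genes lay below 0 in 19 of 19 cases (the same adjusted over the list alone, median -0.79, adjusted p = 3.4e-13, median -0.21 after rescaling). Antioxidant enzyme genes lay below 0 in 22 of 27 cases and lay above 0 in 2 (the same adjusted over the list alone, median -0.63, adjusted p = 2.6e-12, median -0.05 after rescaling). Flavonoid genes lay above 0 in 13 of 23 cases and lay below 0 in 2 (the same adjusted over the list alone, median 0.61, adjusted p = 0.0018, median 1.18 after rescaling). For high light, WRKY genes besides WRKY48 lay below 0 in 8 of 40 cases and lay above 0 in 2 (the same adjusted over the list alone, median -0.06, adjusted p = 0.0041, median -0.12 after rescaling). Heat shock factor genes lay below 0 in 3 of 18 cases (4 adjusted over the list alone, median -0.16, adjusted p = 0.0089).

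In wild type under heat the median was -0.49 for jasmonate response, -1.11 for WRKY and -1.23 for reactive oxygen genes. Between genotypes under heat the jasmonate response list (median 0, adjusted p = 0.86) and the reactive oxygen list (median 0.17, adjusted p = 0.28) were not called, and in control their medians were -0.29 and -0.31. Across genes, the correlation of the genotype differences was 0.302 between control and high light, 0.312 between heat and the combination and -0.015 between control and the combination. Control and high light shared 596 genes called higher and 439 called lower, with 167 of opposite sign, where independent calls would give 133, 97 and 229. Heat and the combination shared 704 and 1821, with 443 of opposite sign, against 354, 807 and 1096. Opposite signs outnumbered the independent value in the other 4 pairs: 529 against 190 between control and heat, 932 against 638 between control and the combination, 830 against 423 between high light and heat, and 1722 against 1394 between high light and the combination. Calls of the same sign also outnumbered it in both directions in 3 of these 4, and between control and the combination only those lower did. An excess in every direction can arise where the same genes are easier to call in each condition. It does not by itself show reversed differences. After rescaling, heat and the combination shared 1781 and 390 with 613 opposite, against 1418, 106 and 940, and control and high light 205 and 761 with 143 opposite, against 33, 242 and 180. Opposite signs then outnumbered the independent value between control and heat (374 against 200) and between high light and heat (455 against 426), and no longer between control and the combination (919 against 1002) or high light and the combination (1824 against 2179). AT1G64795 had means of 58.52, 117.2, 167.8 and 114.7 normalized counts under control, high light, heat and the combination in the libraries labelled wrky48, and at most 0.5684 in wild type. AT2G01422 had means of 135.2, 81.94, 153.4 and 66.15 in wild type and at most 1.06 in the libraries labelled wrky48.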
